A study of Homo sapiens with 6 samples.

How the data were processed

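RNA was taken from PANC-1 cells in 6 samples, 3 labelled shControl and 3 labelled shHDAC5, and groups and replicate numbers come from the labels. Per the labels' protocols, poly(A) RNA was fragmented, copied with random primers and built into libraries with a directional kit. The submitters' processing notes name FastQC, Trimmomatic, HISAT2 2.0.5 and featureCounts 1.5.0-p3, and the build hg19, without roles. The strand setting used in counting is not given in the sources used here, so reads of overlapping and antisense genes are treated as uncertain.

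The deposited table holds raw counts per Ensembl gene, not normalised, and per the file headers an FPKM value beside each count. All 58735 gene IDs are those of GENCODE release 29 on GRCh38, and the exonic length implied by each count and FPKM matches that release within a relative tolerance of 0.0001, unlike the hg19 named in the notes. Coordinates are therefore those of GENCODE release 29 on GRCh38. The authors' FPKM values divide each count by its gene's merged exon length and a scaled library total that lies between 0.9898 and 1.0113 times the summed counts. All 12 columns of sample values were used. The table as given here holds no columns of the authors' own comparison, so a planned overlap with them was not run.

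Library totals lay between 17200847 and 18107742 counts, a depth at which CYP4F12, at a mean of 0.57 CPM in shControl, rested on 6 to 14 counts per library. Chi-square tests of counts between replicates of a group gave 4.25 to 66.05 per degree of freedom, so no pair looked like one library deposited again. The deviations of same-numbered libraries gave no sign of pairing, but 3 libraries per group cannot exclude it.

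Genes were kept by edgeR's filterByExpr by group, counts were scaled by TMM, and edgeR 4.0.16 in R 4.3.3 fitted a robust quasi-likelihood model on group alone, which was tested by its quasi-likelihood F test. Genes were called at a Benjamini-Hochberg adjusted p below 0.05, with no minimum fold. Means and SDs are of TMM-scaled CPM over 3 libraries. Levels of the marker genes are instead means of CPM by library total, over all 6 libraries where no group is named.

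Before the data were examined, 35 gene lists, the tests, the alternatives and the rule for named genes were written down. The lists held 961 entries and covered the arachidonate pathway, chromatin regulators, inflammation and interferon, stress, lipid and energy metabolism, growth, cell identity and markers of other cell types. The 30 lists with at least 5 measured members were tested with limma 3.58.1's camera on log2 CPM (prior count 2) at an inter-gene correlation of 0.01, with camera at an estimated correlation and fry beside it. Camera compares a list with other genes, while fry asks whether a list's genes move on balance one way. HDAC5 and PLA2G4A were always named. The rule then took the 8 largest rises and 8 largest falls among called protein-coding genes with a mean of at least 5 CPM in the higher group and non-overlapping groups, up to 4 called members of each of 4 arachidonate lists, 3 members with the smallest p of every other list called by camera or with at least 5 calls, and the levels of the 2 most abundant members of each marker list; not every gene it took is described in the text.

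After the data were seen, a correction was added in which a loess surface (span 0.4) of each library's log2 deviation on GC content and exonic length, fitted on protein-coding genes with a mean log2 CPM above 3, entered the edgeR model as an offset. GC content was known for 99.95% of tested genes.

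The edgeR step was tested on simulated counts for the comparison of shHDAC5 with shControl, with 200 changed genes among 14839 in 3 runs. Without a GC trend it recovered 79.33% of 2-fold and 19.67% of 1.5-fold changes, and 6.57% of its calls were false. With the GC trends of these libraries it recovered 64.33% and 16%, with 5.87% false. With the correction it recovered 95.67% and 76%, with 9.33% false, above the 5% aimed at. The simulated trends were the surfaces that the correction itself fits, so its gain was partly built in. Runs with the trends also used the lower spread left after correction (common biological coefficient of variation 0.081, against 0.155 in the main fit). Their recovery therefore cannot be set against that of the runs without a trend.

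The alternatives were other scalings and filters, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), the replicate number as a block, stricter thresholds, protein-coding genes alone and leaving out each replicate in turn.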

Results

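Poly(A)-selected RNA from PANC-1, an established human pancreatic carcinoma cell line, was sequenced from cells labelled shControl and from cells labelled shHDAC5, a short hairpin RNA named for the class IIa histone deacetylase HDAC5. Each group held 3 libraries. Gene counts summed to 17200847, 18107742 and 17764335 in shControl replicates 1, 2 and 3, and to 17935611, 17785217 and 17559171 in shHDAC5 replicates 1, 2 and 3. The series title links HDAC5 to arachidonic acid metabolism through cytosolic phospholipase A2, so the comparison asks which transcripts differ between the groups, with those of that enzyme and of the eicosanoid pathway in first place. Nothing in the labels says that the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

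HDAC5 itself (ENSG00000108840, chromosome 17 from 44076746 to 44123702 on the minus strand of GRCh38) was not lower in the libraries labelled shHDAC5. Its counts were 911, 1044 and 1323 in shControl replicates 1, 2 and 3, and 1653, 1329 and 1511 in the libraries labelled shHDAC5. The normalised level was 62.2 ± 11.7 CPM (SD, n = 3) in shControl and 84 ± 9.4 CPM (SD, n = 3) in the libraries labelled shHDAC5. The log2 fold change was 0.43 (SE 0.16, 95% interval 0.07 to 0.8), with an adjusted p of 0.13 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. After correction for GC content and length, a step chosen after the data were seen, it was 0.16 (SE 0.06, 95% interval 0.02 to 0.3) with an edgeR adjusted p of 0.086. Without shControl replicate 3 the log2 fold change was 0.59 and the edgeR adjusted p 0.0016, and with GC and length correction without shControl replicate 1 they were 0.19 and 0.034, within a range of 0.0016 to 0.39 over the alternatives run. HDAC5 mRNA therefore goes against the label, no protein level was measured here, and every direction below is between libraries as labelled. None of the 18 measured histone deacetylases and sirtuins passed the test, over all genes or adjusted over the list alone, and after GC correction 2 rose and 3 fell. HDAC4, another class IIa member, had a log2 fold change of -0.33 (SE 0.12, edgeR adjusted p 0.13).

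The libraries labelled shHDAC5 held more transcripts of fibronectin, the tight junction gene CLDN1, the prostaglandin F synthase AKR1C3 and the lipoxygenase ALOX5. They held less of the kinase MYLK3, intestinal alkaline phosphatase ALPI and the galectin ligand LGALS3BP. Transcripts of the cathepsins CTSL and CTSB were also higher, but those calls ended when any of several single libraries was left out, as given below. FN1, the fibronectin gene, rose from 139 ± 3.02 to 590 ± 6.12 CPM (SD, n = 3), a log2 fold change of 2.09 (SE 0.09), and 2.13 with GC and length correction. Of 15053 genes tested, 902 passed an edgeR adjusted p of 0.05, 660 higher and 242 lower, so that 73.2% of the calls were higher. With GC and length correction 3938 genes passed, 1874 higher and 2064 lower, so that 47.6% were higher. Of the 902 genes, 872 passed the corrected test in the same direction. The groups did not overlap for 32.1% of tested genes, against 10% by chance.

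**Figure D1:**
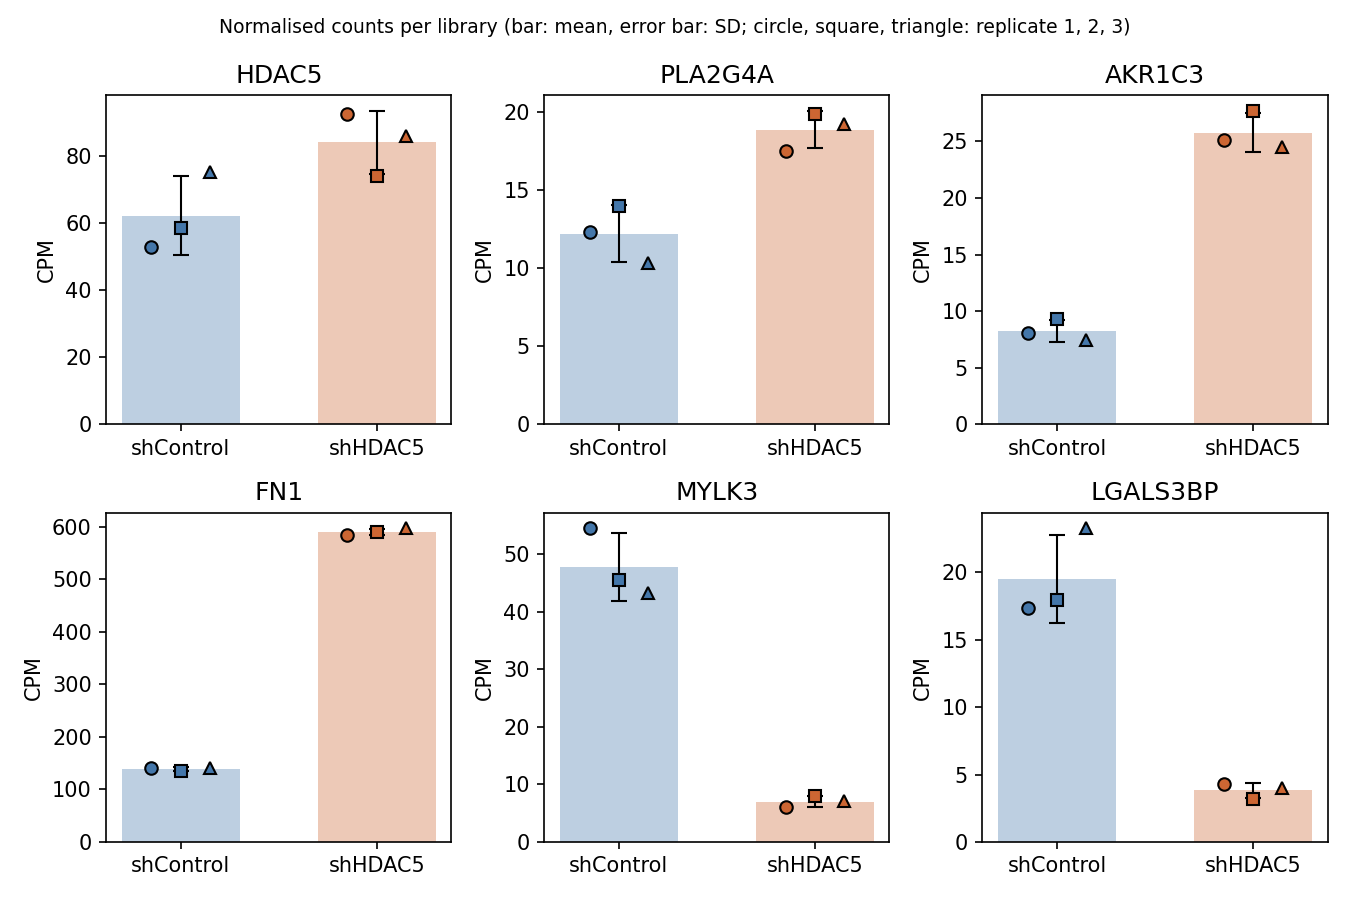
Normalised counts (CPM) of 6 genes in each library, grouped as labelled, with bars for the mean, error bars for the SD and one point per replicate. HDAC5 averaged 62.2 CPM in shControl and 84 CPM in the libraries labelled shHDAC5, PLA2G4A 12.2 and 18.9 CPM, and FN1 139 and 590 CPM.

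Single libraries weighed on that count. It was 158 without shControl replicate 2, 6813 without shControl replicate 3, and 209, 261 and 204 without shHDAC5 replicates 1, 2 and 3, against 902 with all libraries. Among 52 named genes other than HDAC5 and PLA2G4A, those whose call ended numbered 2 and 23 without shControl replicates 1 and 2, and 19, 14 and 17 without shHDAC5 replicates 1, 2 and 3. A log2 fold change of at least 1 was reached by 387 genes, 340 higher and 47 lower.

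PLA2G4A, which encodes cytosolic phospholipase A2, the enzyme that frees arachidonic acid from membrane phospholipids, rose from 12.2 ± 1.84 to 18.9 ± 1.21 CPM (SD, n = 3) in the libraries labelled shHDAC5. The gene (ENSG00000116711) lies on chromosome 1 from 186828953 to 186988981 on the plus strand of GRCh38. Its log2 fold change was 0.63 (SE 0.15, 95% interval 0.29 to 0.97, edgeR adjusted p 0.046), and 0.89 (SE 0.11, edgeR adjusted p 0.00013) with GC and length correction. The uncorrected call lay at the threshold: the edgeR adjusted p was 0.066 and 0.098 without shControl replicates 1 and 2, and 0.14, 0.15 and 0.2 without shHDAC5 replicates 1, 2 and 3, within a range of 1.7e-05 to 0.2 over the alternatives run.

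Among 12 measured phospholipases A2, 2 rose, none fell and 10 did not pass, with the same counts adjusted over the list alone, and with GC correction 2 rose and 1 fell. Besides PLA2G4A, the lysosomal phospholipase PLA2G15 rose from 37.7 ± 6.39 to 60.8 ± 1.04 CPM (SD, n = 3; log2 fold change 0.69, SE 0.14, edgeR adjusted p 0.028). As a list they did not differ from other genes (camera adjusted p 0.2, and adjusted p = 0.38 with an estimated correlation). In fry, which makes no comparison with other genes, the list was higher (adjusted p 0.0015). It passed in fry with GC correction too (adjusted p 0.011). Fry passed 17 of the 30 tested lists, so passing it does not set a list apart.

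Of 26 measured genes of eicosanoid synthesis and breakdown, 4 rose, none fell and 22 did not pass, and adjusted over the list alone 7 rose and 2 fell. With GC correction 6 rose and 2 fell. AKR1C3, a prostaglandin F synthase, rose from 8.27 ± 0.969 to 25.8 ± 1.7 CPM (SD, n = 3; log2 fold change 1.64, SE 0.14, and 1.81 with GC correction). ALOX5, the lipoxygenase that opens leukotriene synthesis, rose by 2.00 on the log2 scale (SE 0.25, and by 1.76 with GC correction) from a mean of 1.1 CPM, and the aldose reductase AKR1B1 by 0.86 (SE 0.14) from a mean of 87.8 CPM. CYP4F12, a fatty acid hydroxylase, rose by 1.67 (SE 0.36) from a mean of 0.57 CPM. AKR1C3 and CYP4F12 have related family members, and reads shared with them cannot be assigned from these counts. Of the relatives of CYP4F12, CYP4F2, CYP4F3 and CYP4F11 had totals of 2, 1 and 3 counts over all libraries. The cyclooxygenase PTGS2, with 32 counts over all libraries, was too low to test, and the cyclooxygenase PTGS1 did not pass at a log2 fold change of 0.35 (SE 0.11, edgeR adjusted p 0.1, and 0.042 with GC correction), like the thromboxane synthase TBXAS1 at 0.33 (SE 0.22, edgeR adjusted p 0.34). The list was higher by camera (adjusted p 0.0038). That call was lost with GC correction (adjusted p 0.11) and with an estimated correlation (adjusted p 0.28). In fry the list was higher (adjusted p 0.0065), and it passed with GC correction too (adjusted p 0.002).

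Of 8 measured eicosanoid receptors and transporters, 1 rose and 7 did not pass, with the same counts adjusted over the list alone, and with GC correction 1 rose and 1 fell. The gene that rose was PTGER4, a prostaglandin E receptor, which rose from 9.28 ± 0.525 to 17.9 ± 1.12 CPM (SD, n = 3; log2 fold change 0.95, SE 0.13, edgeR adjusted p 0.0054) and overlaps TTC33 on the opposite strand. The list had a camera adjusted p of 0.42 (adjusted p = 0.65 with an estimated correlation), and its median log2 fold change moved from 0.12 to -0.11 with GC correction. Its fry adjusted p was 0.064, and 0.58 with GC correction. Without GC correction none of 33 measured genes of arachidonate remodelling and polyunsaturated fatty acids passed, over all genes or adjusted over the list alone, and with it 9 rose and 4 fell (uncorrected camera adjusted p 0.098, and adjusted p = 0.28 with an estimated correlation). In fry this list was higher (adjusted p 0.01), and it passed with GC correction too (adjusted p 0.00056). FADS1, a desaturase of arachidonate synthesis, stood at a log2 fold change of 0 (SE 0.09), and the monoacylglycerol lipase MGLL at 0.45 (SE 0.13, edgeR adjusted p 0.073), and at 0.34 with an edgeR adjusted p of 0.00049 with GC correction. Leaving out single libraries did not end the calls of AKR1C3 and ALOX5. The edgeR adjusted p of PTGER4 was 0.053 without shControl replicate 2, and that of AKR1B1 was 0.071 without shControl replicate 2 and 0.069 and 0.062 without shHDAC5 replicates 1 and 3. For PLA2G15 it was 0.15 without shControl replicate 2, and 0.13, 0.1 and 0.13 without shHDAC5 replicates 1, 2 and 3. For CYP4F12 it was 0.063 and 0.14 without shControl replicates 1 and 2, and 0.088, 0.11 and 0.17 without shHDAC5 replicates 1, 2 and 3.

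Among protein-coding genes with non-overlapping groups and a mean of at least 5 CPM in the higher group, the 8 largest rises included TNNT1, slow skeletal troponin T, from 0.663 ± 0.463 to 15.8 ± 1.83 CPM (SD, n = 3; log2 fold change 4.56, SE 0.34). The others were the Wnt pathway inhibitor NKD2 (log2 fold change 3.57, SE 0.27), TMEM151A (3.25, SE 0.26), the sterol exporter ABCG1 (2.97, SE 0.27), PDZD4 (2.91, SE 0.18), DNER (2.89, SE 0.27), the T-type calcium channel CACNA1G (2.63, SE 0.17) and the synaptic vesicle priming factor UNC13A (2.41, SE 0.24). Among the largest falls under the same limits, MYLK3, a myosin light chain kinase of heart muscle, went from 47.7 ± 5.93 to 6.97 ± 0.957 CPM (SD, n = 3; log2 fold change -2.77, SE 0.16). ALPI had a log2 fold change of -2.76 (SE 0.25) and LGALS3BP of -2.35 (SE 0.18). MUC13, a transmembrane mucin, followed at -1.55 (SE 0.24), then TOGARAM2 at -1.46 (SE 0.27), GIPC3 at -1.44 (SE 0.15), GPR89B at -1.34 (SE 0.18) and the actin-binding NEXN at -1.32 (SE 0.28). All 16 also passed with GC and length correction. Without shControl replicate 2 the uncorrected edgeR adjusted p was 0.06 for MUC13, 0.061 for TOGARAM2 and 0.15 for NEXN. For TOGARAM2 it was also 0.097 and 0.087 without shHDAC5 replicates 1 and 2. For NEXN it was also 0.055 without shControl replicate 1, and 0.12, 0.058 and 0.14 without shHDAC5 replicates 1, 2 and 3. ALPI and GPR89B have closely related copies. GPR89A stood at a log2 fold change of 0.31 (edgeR adjusted p 0.323), so the split of reads between the copies is uncertain.

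Of 25 measured YAP and TGF-beta targets 9 rose and none fell, adjusted over the list alone 13 rose, and with GC correction 10 rose and 2 fell (camera adjusted p 6.9e-05, but adjusted p = 0.19 with an estimated correlation). The ectonucleotidase NT5E rose by 1.54 (SE 0.15) and the activin-binding FST by 1.14 (SE 0.12) on the log2 scale. Of 20 measured mesenchymal genes 3 rose, FN1, the fibronectin receptor subunit ITGA5 (0.94, SE 0.11) and COL5A1 (0.71, SE 0.14), none fell, and adjusted over the list alone 8 rose and 1 fell, as with GC correction (camera adjusted p 0.0041, but adjusted p = 0.28 with an estimated correlation). Of 20 measured epithelial genes 8 rose and none fell, 9 adjusted over the list alone, while with GC correction 9 rose and 4 fell (camera adjusted p 0.00048, but adjusted p = 0.33 with an estimated correlation). They included the tight junction protein CLDN1 (1.28, SE 0.14), the laminin chain LAMB3 (1.25, SE 0.17) and the desmosomal DSP (0.83, SE 0.11). The edgeR adjusted p was 0.052 for LAMB3 without shControl replicate 2 and 0.054 for DSP without shHDAC5 replicate 3. For COL5A1 it was 0.14 without shControl replicate 2, and 0.13, 0.081 and 0.11 without shHDAC5 replicates 1, 2 and 3.

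Of 30 measured immediate early genes and MAPK outputs 5 rose and none fell, 12 adjusted over the list alone (camera adjusted p 0.00019, but adjusted p = 0.31 with an estimated correlation). With GC correction 11 rose and 4 fell, and the list's median moved from 0.42 to 0.14. EGR1 rose by 2.24 (SE 0.31, and by 2.08 with GC correction) from a mean of 0.964 CPM, JUN by 1.13 (SE 0.18) and the MAPK feedback inhibitor SPRY4 by 0.92 (SE 0.13). Of 11 measured neuronal and endocrine genes 4 rose and none fell, with the same counts adjusted over the list alone and with GC correction (camera adjusted p 0.00049, but adjusted p = 0.28 with an estimated correlation). The prohormone convertase PCSK1 rose by 1.62 (SE 0.22), the neuronal enolase ENO2 by 0.94 (SE 0.14) and the synaptic SNAP25 by 2.45 (SE 0.33) from a mean of 0.435 CPM. Of 37 measured lysosome and autophagy genes 7 rose and none fell, and adjusted over the list alone 14 rose and 2 fell, and with GC correction 16 rose and 3 fell (camera adjusted p 0.00087, but adjusted p = 0.28 with an estimated correlation). The cathepsins CTSL and CTSB rose by 0.83 (SE 0.14) and 0.59 (SE 0.11). The progranulin gene GRN rose by 0.62 (SE 0.12, edgeR adjusted p 0.027), a call that ended with GC correction at 0.25 (SE 0.1, edgeR adjusted p 0.094). Without shControl replicate 2 the uncorrected edgeR adjusted p was 0.1 for CTSL, 0.12 for CTSB, 0.15 for GRN, 0.073 for JUN, 0.052 for SPRY4 and 0.071 for ENO2. Without shHDAC5 replicates 1, 2 and 3 it was 0.085, 0.057 and 0.081 for CTSL, 0.11, 0.068 and 0.12 for CTSB, and 0.13, 0.061 and 0.14 for GRN. For JUN it was 0.07 and 0.059 without shHDAC5 replicates 1 and 2, and for ENO2 it was 0.058 without shHDAC5 replicate 1.

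**Figure D2:**
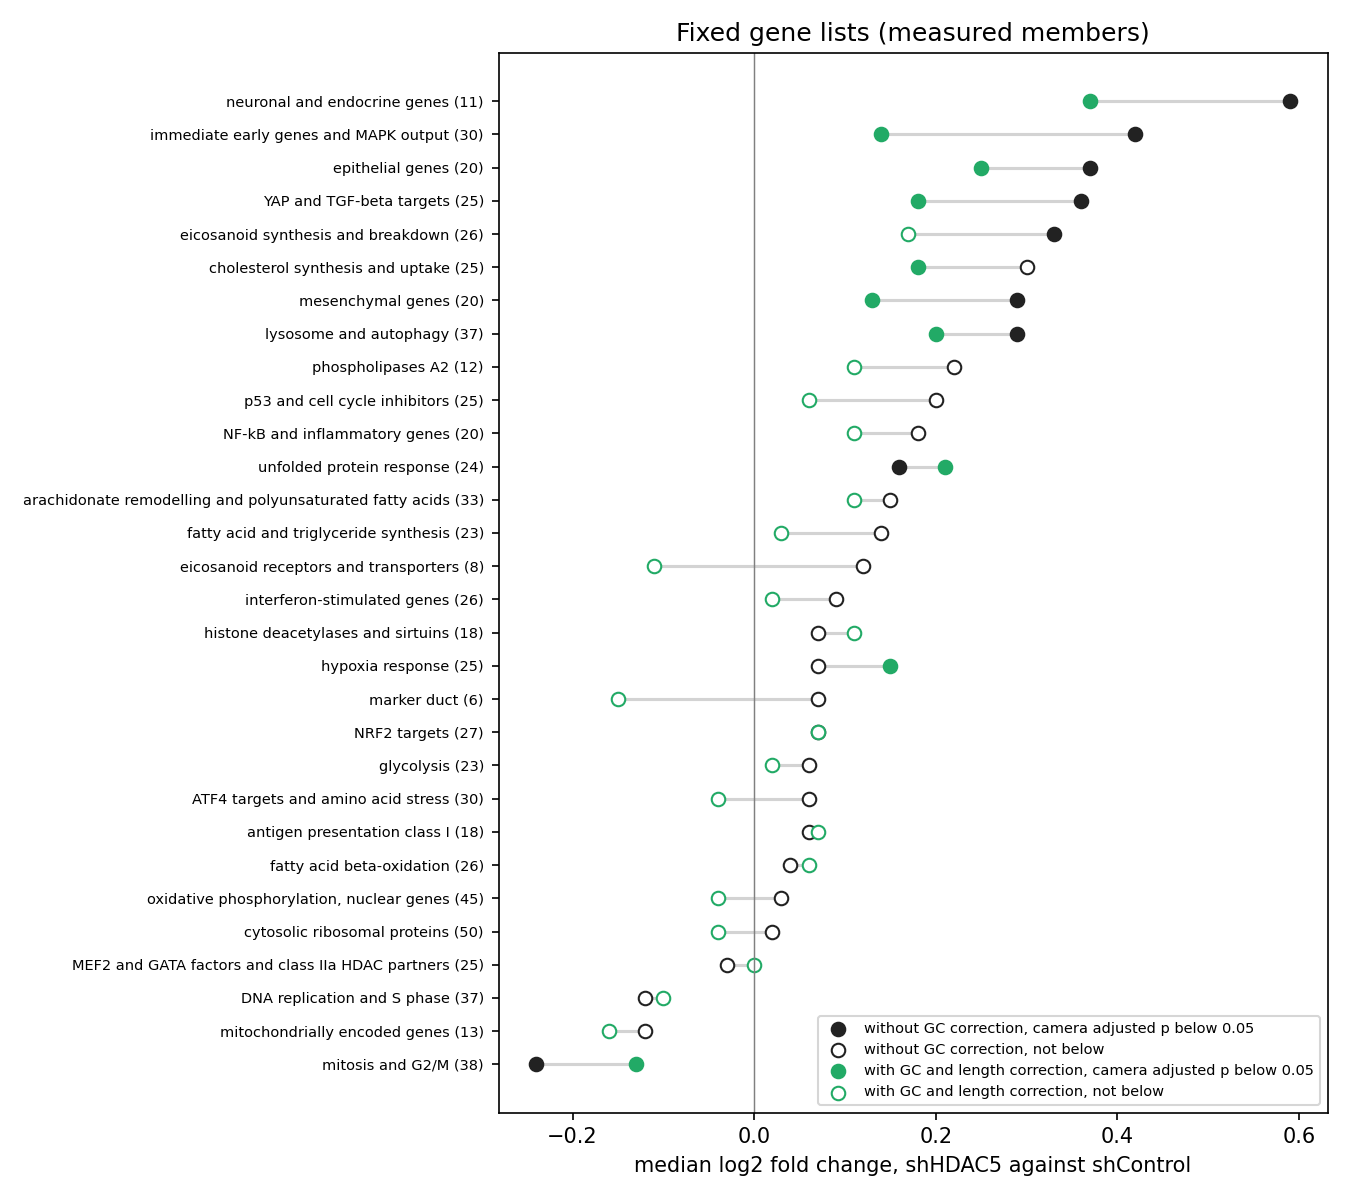
Median log2 fold change of the members of each of 30 fixed gene lists, libraries labelled shHDAC5 against shControl, with measured members in brackets, before and after GC and length correction, and filled points where camera's adjusted p lay below 0.05. The neuronal and endocrine list moved from 0.59 to 0.37 and the mitosis list from -0.24 to -0.13.

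Of 24 genes of the unfolded protein response 2 rose, the chaperone CALR (0.76, SE 0.13) and MANF (0.78, SE 0.18), none fell, and 6 rose adjusted over the list alone (camera adjusted p 0.023, but adjusted p = 0.28 with an estimated correlation). With GC correction 14 rose and none fell. Without shControl replicate 3 and without shHDAC5 replicate 2 the list was not called (camera adjusted p 0.17 and 0.052). The edgeR adjusted p of MANF was 0.17 without shControl replicate 2, and 0.19, 0.086 and 0.17 without shHDAC5 replicates 1, 2 and 3, and that of CALR was 0.094 without shControl replicate 2 and 0.079 and 0.081 without shHDAC5 replicates 1 and 3. CRELD2 had a log2 fold change of 0.6 (SE 0.16, edgeR adjusted p 0.069) and overlaps ALG12. The list of mitosis and G2/M genes was lower by camera (adjusted p 0.00049, but adjusted p = 0.44 with an estimated correlation), although 1 of 38 members fell, 37 did not pass and the counts adjusted over the list alone were the same. With GC correction 11 fell and 1 rose. The gene that fell without correction was the kinetochore motor CENPE (log2 fold change -1.03, SE 0.2, edgeR adjusted p 0.026), which has a GC content of 35.5% and stood at -0.6 (SE 0.07) with GC correction. The uncorrected edgeR adjusted p of CENPE was 0.14 without shControl replicate 2, and 0.13, 0.076 and 0.12 without shHDAC5 replicates 1, 2 and 3. CENPN, which overlaps CMC2, stood at -0.5 (SE 0.15, edgeR adjusted p 0.084, and 0.0049 with GC correction), and BUB1 at -0.39 (SE 0.12, edgeR adjusted p 0.1, and 0.025 with GC correction). Of 9 lists called by camera, none was called with an estimated correlation, where the lowest adjusted p was 0.19 and the lowest unadjusted p 0.0062. In fry 17 of the 30 tested lists passed, among them 8 of these 9. The mitosis list passed in fry only with GC correction (adjusted p 0.064 without, 0.0037 with). Without correction fry also passed lists that camera did not. Replication genes were lower (adjusted p 0.0046). Higher were NRF2 targets (0.0024) and the cholesterol (0.0046), interferon (0.0052), hypoxia (0.017), p53 (0.025) and MEF2 and GATA (0.026) lists. Of these, all but the MEF2 and GATA list (0.3) passed in fry with GC correction.

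Of 25 hypoxia genes 5 rose, among them the lipase inhibitor ANGPTL4 (1.27, SE 0.15), the carbonic anhydrase CA12 (0.87, SE 0.14) and ADM (0.8, SE 0.13), none fell, and 6 rose adjusted over the list alone (camera adjusted p 0.11, and 0.0043 with GC correction, where 11 rose and 2 fell). Of 25 genes of cholesterol synthesis and uptake 1 rose and 24 did not pass, and 4 rose adjusted over the list alone (camera adjusted p 0.056, and 0.0014 with GC correction, where 9 rose and 1 fell). With an estimated correlation and GC correction both lists had an adjusted p = 0.17. Of 30 ATF4 targets and amino acid stress genes 3 rose and 2 fell, and adjusted over the list alone 4 rose and 2 fell (camera adjusted p 0.69), with a median that moved from 0.06 to -0.04 with GC correction, where 6 rose and 6 fell. CHAC1, which degrades glutathione, rose by 1.34 (SE 0.24), the lipoprotein receptor VLDLR by 0.81 (SE 0.15) and STC2 by 0.7 (SE 0.14), while CTH and PSPH, named after their values were seen, stood at -0.69 (SE 0.16) and -0.61 (SE 0.13). Without shControl replicate 2 the edgeR adjusted p was 0.088 for CHAC1, 0.1 for VLDLR, 0.13 for STC2, 0.08 for CA12 and 0.09 for ADM. Without shHDAC5 replicates 1, 2 and 3 it was 0.079, 0.053 and 0.095 for CHAC1, 0.13, 0.085 and 0.12 for STC2, and 0.071, 0.064 and 0.061 for CA12. Without shHDAC5 replicates 1 and 3 it was 0.097 and 0.12 for VLDLR, and 0.076 and 0.071 for ADM.

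Members of the lists that follow were named after their values were seen. With GC correction the members higher and lower numbered 9 and 4 for NRF2 targets, 7 and 3 for p53 genes, 5 and 4 for inflammatory genes, 8 and 3 for antigen presentation, 4 and 3 for interferon-stimulated genes and 4 and 2 for MEF2 and GATA factors. The counts for each list below are without that correction. Of 27 NRF2 targets 4 rose, among them AKR1C3, HMOX1 and ABCC3, with 6 adjusted over the list alone (camera adjusted p 0.16). Of 25 p53 and cell cycle inhibitor genes CDKN1A (1.27, SE 0.14) and CDKN2B (1.22, SE 0.11) rose and ZMAT3 (-0.84, SE 0.17) fell, with 6 higher and 2 lower adjusted over the list alone (camera adjusted p 0.13). Of 20 NF-kB and inflammatory genes CXCL8 and LIF rose and TNFAIP3 and REL fell, with 4 higher and 2 lower adjusted over the list alone (camera adjusted p 0.31). CXCL8 was barely detected, at means of 0.0754 CPM in shControl and 0.767 CPM in the libraries labelled shHDAC5. Of 18 class I antigen presentation genes 3 rose, among them CALR and HLA-B, with 7 higher and 3 lower adjusted over the list alone (camera adjusted p 0.31), and HLA genes share reads. Of 26 interferon-stimulated genes IFI6 rose (1.49, SE 0.19) and 25 did not pass, also adjusted over the list alone (camera adjusted p 0.52). Of 25 MEF2 and GATA factors and class IIa HDAC partners KLF6 (0.63, SE 0.11) and RUNX2 (1.64, SE 0.29) rose, also adjusted over the list alone, and the list's median of -0.03 and camera's direction of higher differed in sign (camera adjusted p 0.54).

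In metabolism, of 23 genes of fatty acid and triglyceride synthesis ACSS2 and GPAT3 rose and LPIN1 fell, with 3 higher and 1 lower adjusted over the list alone (camera adjusted p 0.16). Of 23 glycolysis genes ENO2 rose, which overlaps LRRC23, also adjusted over the list alone (camera adjusted p 0.17). Of 45 nuclear genes of oxidative phosphorylation UQCRC2 fell (-0.46, SE 0.11), a call not held adjusted over the list alone, and the list's median of 0.03 and camera's direction of lower differed in sign (camera adjusted p 0.69), the median being -0.04 with GC correction. Without GC correction none of 26 genes of fatty acid beta-oxidation (camera adjusted p 0.69), 13 mitochondrially encoded genes (0.22), 50 cytosolic ribosomal protein genes (0.96) or 37 genes of DNA replication and S phase (0.17) passed, over all genes or adjusted over the list alone. As a list the replication genes were lower in fry (adjusted p 0.0046), and they passed in fry with GC correction too (adjusted p 0.014). With GC correction 3 replication genes rose and 10 fell, and no ribosomal protein gene rose and 7 fell. With it 1 beta-oxidation gene rose and 1 fell, and 1 mitochondrially encoded gene fell. Fatty acid synthesis then held 7 higher and 1 lower, glycolysis 5 and 4, and oxidative phosphorylation 1 and 6. For the ribosomal proteins the median of 0.02 and mean of 0.04 differed in sign from camera's direction of lower, and the median was -0.04 with GC correction. The camera adjusted p of the 18 histone deacetylases and sirtuins was 0.49.

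Markers of other pancreatic and stromal cells were low or mixed, with levels given here as CPM by library total, without TMM scaling. Of 6 measured duct markers SOX9 rose (0.94, SE 0.18), the most abundant, KRT7, averaged 1349 CPM in shControl and 1537 CPM in the libraries labelled shHDAC5, and ONECUT2 averaged 125 and 92.6 CPM (camera adjusted p 0.77), with a list median of 0.07 that was -0.15 with GC correction. The other marker lists had fewer than 5 measured members and were not tested as lists. Of 20 acinar markers 2 were measured, BHLHA15 at a mean of 3.53 CPM and CEL at 0.71 CPM, and of 17 leukocyte markers 2 were measured, LAPTM5 at 0.98 CPM among them, with none past the threshold over all genes, and 1 acinar gene higher and 1 leukocyte gene lower adjusted over the list alone. Among islet markers MAFA rose (1.27, SE 0.23) from 2.39 CPM. Among fibroblast markers FBLN1 averaged 595 and 835 CPM (edgeR adjusted p 0.061), COL1A1 12.1 and 14.9 CPM (edgeR adjusted p 0.43), and PDGFRB fell (-0.91, SE 0.17). Among endothelial markers ESAM rose (1.27, SE 0.18) from 17 CPM, while CDH5 averaged 2.3 and 2.08 CPM (edgeR adjusted p 0.68).

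Levels also followed the GC content of genes, differently in each library. The slope of log2 level on GC content, per 10 percentage points, was -0.4, -0.192 and 0.176 in shControl replicates 1, 2 and 3, and 0.246, 0.035 and 0.135 in shHDAC5 replicates 1, 2 and 3. Across genes, which are not independent replicates, the log2 fold change had a Spearman rho of 0.67 with GC content and 0 after correction. The 0 is built in, because the correction was fitted on the GC content of these same genes. The genes called higher had a median GC content of 54.8%, those called lower 45.1% and all tested genes 49.3%.

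**Figure D3:**
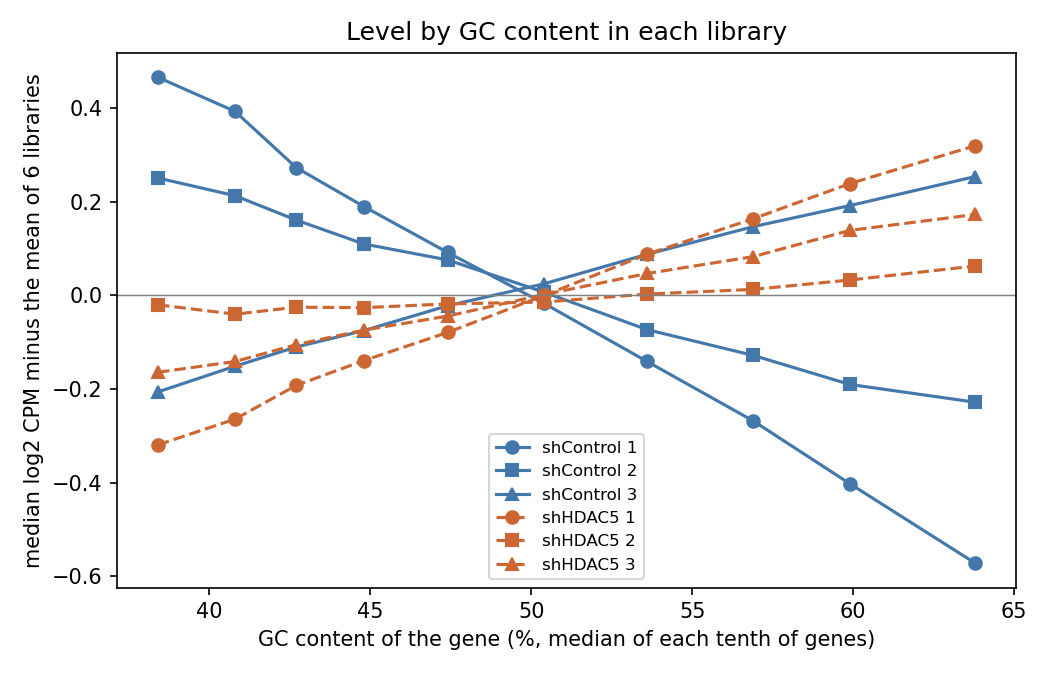
Median log2 CPM of genes in 10 equal groups by GC content, relative to the mean of the 6 libraries, against GC content in percent, with one line per library. The line of shControl replicate 1 falls from 0.47 to -0.57 and that of shHDAC5 replicate 1 climbs from -0.32 to 0.32.

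**Figure D4:**
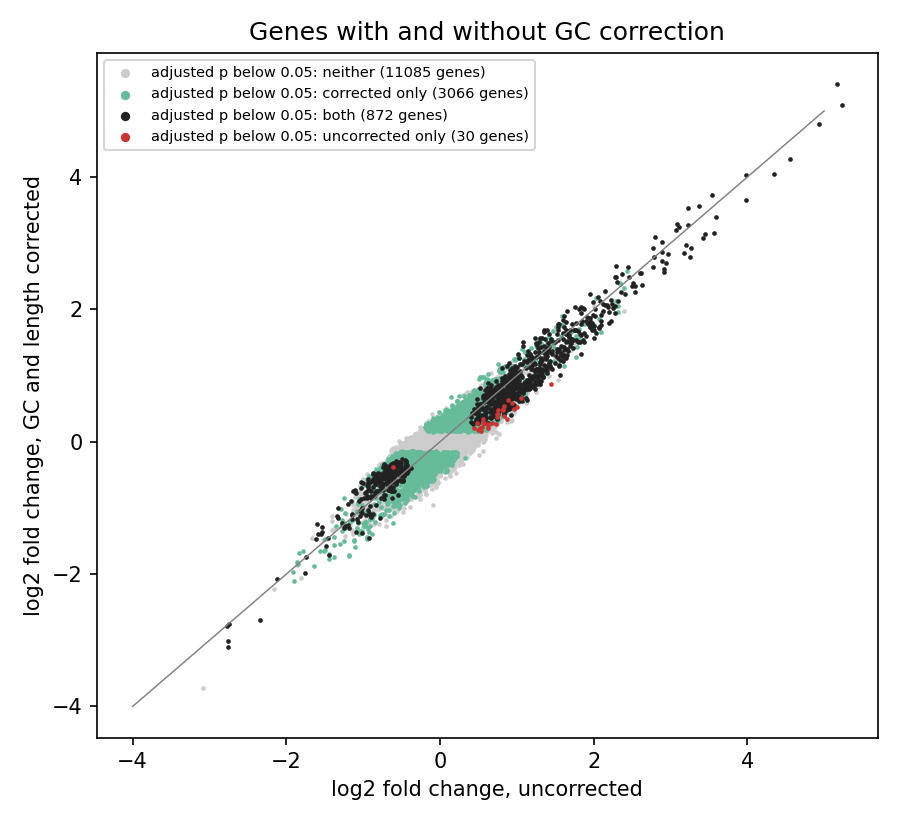
Log2 fold change of each of 15053 genes without (x axis) and with (y axis) GC and length correction, coloured by which of the edgeR tests it passed, with a line of equality. 872 genes passed both tests and 30 passed only the uncorrected one.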

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

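The alternatives with GC and length correction were chosen after seeing the data. The count of changed genes, 902, stayed within 1.5 times under RLE (870), upper-quartile (919) and total-count scaling (883), a CPM filter (891), limma-voom (982), limma on FPKM (775 and 736) and protein-coding genes alone (819). It was 1634 with no low-count filter and 1896 in DESeq2, and 218, 387 and 419 at an adjusted p below 0.01, a log2 fold change of at least 1 and a minimum fold of 1.2, which are stricter by construction. Leaving out 1 replicate gave 158 genes without shControl replicate 2 and 6813 without shControl replicate 3. It gave 694 without shControl replicate 1 and 209, 261 and 204 without shHDAC5 replicates 1, 2 and 3. Fewer samples tend to lower a count, which does not account for the rise without shControl replicate 3. That library lay between the groups, as described below, and the cause of these shifts in count was not otherwise tested. GC and length correction called 3938 genes, 3841 without shControl replicate 1 and 5391 without shControl replicate 3. Same-numbered libraries had correlations of -0.34, 0.15 and -0.01 in their deviations, and of -0.09, 0.07 and 0.01 with GC correction. This gave no sign of pairing, but 3 libraries per group cannot exclude it. A replicate block gave 429 genes, and 3535 with GC correction. HDAC5 had a log2 fold change of 0.34 to 0.59 when 1 replicate was left out, passing at 0.59, and of 0.19, passing, with GC correction without shControl replicate 1; it stayed above 0 in each alternative run. PLA2G4A ranged from 0.52 to 0.74 when 1 replicate was left out, and missed the threshold at 0.54 and 0.63 with limma on FPKM and at 0.64 with the replicate block; the cause was not tested. Of 52 other named genes, 25 kept their call under each of 20 alternatives, and none changed direction. The replicate block ended the calls of PLA2G15 (adjusted p 0.066), CYP4F12 (0.054), VLDLR (0.066), STC2 (0.059), MANF (0.082), COL5A1 (0.054), CTSB (0.061) and GRN (0.053), and limma on FPKM ended those of TOGARAM2 (FPKM + 1), NEXN (FPKM + 0.1) and MANF (both). For all of them together, 90 results fell short and 18 came to pass. Without GC correction camera called 9 of 30 gene lists, 8 to 11 when 1 replicate was left out, and 0 with an estimated correlation. In fry 17 of the 30 passed, 8 of them among those 9. With the replicate block and no GC correction 8 were called, without the unfolded protein response (camera adjusted p 0.055). With GC correction camera called 10 lists, 8 of them among those 9, and 0 with an estimated correlation. It then called 10 with the replicate block and 12 without shControl replicate 3. At this depth low-level genes such as CYP4F12 rest on 6 to 40 counts per library.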

Other observations

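The gene families here, the GC slope ratio, the bounds on HDAC5, the place of shControl replicate 3, both tests of mixed RNA and the count of split genes without correction were tests chosen only after the result was seen. Families were picked by symbol after the gene table had been read, so they describe these libraries and do not stand as independent tests. With correction 14.4% of 12195 protein-coding genes were higher and 15.3% lower, the shares against which families were tested. Of 10 measured integrins, 9 were higher and none lower in the libraries labelled shHDAC5 with GC and length correction (Fisher's exact test, adjusted p 3.9e-06 over 34 tests of 17 families), and 5 were higher without it. ITGB4 rose by 1.11 (SE 0.18) on the log2 scale to a mean of 1190 CPM, and ITGA3 by 1.19 (SE 0.13). Of 18 collagens, 12 were higher with correction (Fisher's exact test, adjusted p 7.1e-06) and 4 without, COL4A6 rising by 1.32 (SE 0.13). Of 11 S100 genes, 7 were higher with correction (adjusted p 0.0017) and 3 without, and of 8 fibroblast growth factor ligands, binding proteins and receptors, 6 and 3 (adjusted p 0.0016), FGFR1 rising by 1.38 (SE 0.15) and FGFBP1 by 1.83 (SE 0.2). The medians of these 4 families stayed above 0 under each scaling run. The scalings without GC correction hardly differed, with a median over all genes of -0.01 to 0.02, so they could not have changed these signs.

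All 4 measured alkaline phosphatases were lower with GC correction (Fisher's exact test, adjusted p 0.0031), where ALPP stood at -1.04 (SE 0.05) and ALPI at -3.1 (SE 0.15), although ALPI was the 1 that passed without it, and reads shared among ALPP, ALPG and ALPI are uncertain. Of 18 aminoacyl-tRNA synthetases, 8 were lower with correction (adjusted p 0.013) and 1, LARS, without (log2 fold change -0.56, SE 0.13). Of 393 ZNF zinc finger genes, 14 were higher with correction, a smaller share than the 14.4% of 12195 protein-coding genes (Fisher's exact test, adjusted p 3.1e-11). For their share of lower calls the test did not pass (48 genes, adjusted p 0.19). The medians of the phosphatases and synthetases stayed below 0 under each scaling run, with the same limit on the scalings without GC correction.

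The GC slopes of the shControl libraries lay further apart than the groups did. The slope of shControl replicate 3 minus replicate 1 was 0.576 log2 per 10 points of GC, 2.08 times the 0.277 between group means, which argues against the hairpin group alone setting the trend. The same slope held among 93 ribosomal-protein and respiratory-chain genes (0.475, SE 0.081) and among 1772 non-coding genes (0.538, SE 0.018), the lower being 0.82 of that of all genes. This is in line with a bias of library preparation or sequencing by GC content, a candidate explanation that no label on batches lets one pursue. A part of the group difference in slope that comes from the cells stays open.

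HDAC5 mRNA was not lower in the libraries labelled shHDAC5. The lower bound of its GC-corrected 95% interval, 0.02, argues against a fall of HDAC5 mRNA to 50% or less, and the upper bound, 0.3, against exchanged group labels with such a fall. The uncorrected log2 fold change of 0.43 lay at the 79.3rd percentile of 217 genes alike in GC content, length and level (75.5 without matching on level), whose median was 0.21, so the GC trend is consistent with much of the rise. A hairpin that lowers the protein without the mRNA, a weak hairpin and a mix-up with samples outside this set stay open, and none was tested.

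Along the main axis of variation, which held 60.4% of the variance, shControl replicate 3 lay at 0.65 of the way from the other controls to the shHDAC5 mean. With GC correction the main axis was computed anew and held 54.8% of the variance, and on it this library lay at 0.25. The GC trend is therefore a candidate explanation of the larger part. The 2 positions lie on different axes, so a change of axis may account for some of the drop. For RNA of the other group mixed into it, the share estimated from 10 genes lower by at least 1.5 on the log2 scale was 0.38 (bootstrap interval 0.17 to 0.77), and from 56 genes higher it was 0.03 (0 to 0.07). The upper bound of 0.07 argues against a mixture as large as 0.25, and a cutoff of 1 gave 0.43 and 0.04. A smaller mixture cannot be told apart from variation between these samples, since the shares of the higher and lower genes differ and the lower genes are few.

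Other splits of the 6 libraries into 3 and 3 gave at most 0 changed genes, against 902 for the real split, and also at most 0 with GC correction, against 3938. They called up to 6 gene lists by camera, against 9. In each case 1 of 10 splits, the real one, reached the observed count, and 10 splits are too few for a share under 0.05. Every other split mixed both groups on each side, so a group difference would itself add spread and keep its calls few. These counts are therefore not those expected without a group difference.

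A hypothesis for the neuronal genes that rose, such as SNAP25, was release from the neuronal repressor REST. The test used 50 known REST targets, of which 23 were measured. The targets were meant to leave out genes seen in earlier results. SYP and VGF, at -0.22 and -0.23 with GC correction, nonetheless also belong to the neuronal and endocrine list above. The median GC-corrected log2 fold change of the 23 targets was 0.19. It lay at the 92.4th percentile of 10000 random lists matched on level and GC content. This was short of the 95th percentile set beforehand, so the test does not decide. With correction 8 of the 23 rose and 2 fell, CHD5 rising by 1.49 and SEZ6L2 by 0.56, while REST mRNA stood at -0.14 (SE 0.1, edgeR adjusted p 0.36).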
